A study of Mus musculus with 15 samples.

How the data were processed

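Polyadenylated RNA of 15 libraries was sequenced with a stranded mRNA kit, per the labels' protocols, and the authors deposited a separate table of FPKM per gene symbol for each line. FPKM, fragments per kilobase of gene and per M mapped fragments, was computed by the authors before deposit, and the submitters' processing notes name the GRCm39 build and DESeq2 without versions. The aligner, the counter and the annotation are not given in the sources used here. There were 54343 gene entries for MC38 and 55303 for B16-F10, of which 23483 and 23264 were above 0 in any library. Columns summed to between 482580 and 511160, so the values are not scaled to a common total. Each column was matched to its sample by its label, with 0 columns left unmatched. The tissue label reads melanoma for both lines, whereas MC38 is a colon adenocarcinoma line and its column names say colon. The labels name no vector-only MC38 group, and wild-type MC38 libraries served as control.

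Depth was estimated from low FPKM values, which are whole multiples of the value of 1 fragment when a gene's length is known. Lengths came from single-transcript genes of GENCODE M21, on GRCm38, an earlier assembly than that of the authors, so no coordinates are given. This annotation was used only for lengths, for chromosome membership and for the order of genes along chromosome 14. Of the low values 80.9 to 85.6% lay within 0.1 of a whole number, and depth came to 32.6 to 48.9 M fragments per library. Whole reads could not be recovered for nearly all genes, so count models were not used. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 5.38 to 30.8), and all were counted as separate samples.

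Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a mean-variance trend, on genes with a mean FPKM of at least 1 within the line, and p-values were adjusted by the Benjamini-Hochberg method. A fold change on this scale understates the change of low genes. Each line was fitted alone. Gene lists, 24 in number, were fixed before the data were examined, together with tests, alternatives and the rule for naming genes. Of the listed genes 6 were matched by an older symbol. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Exact permutation tests were two-sided. On simulated data for MC38, over 10748 genes, 93% of genes changed 1.5-fold and 98% of genes changed 2-fold were recovered and 4.67% of calls were false. For B16-F10, over 10902 genes, the shares were 90%, 98% and 3.42%. A planted list was called and 0 of 23 unchanged lists were. Noise was drawn independently for each gene, so the simulation does not show how the list test behaves when genes vary together. Only 200 genes were changed besides the planted list, and no spread shared across genes of a library was simulated. The shares of recovered and false calls therefore need not hold for the real libraries.

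The naming rule took Ssbp4, every measured cholesterol enzyme, and per line the 8 highest and 8 lowest fold changes among called genes whose groups did not overlap and whose higher group mean was at least 5 FPKM, leaving out predicted and clone names. It also took up to 2 highest and 2 lowest called members per list, or up to 2 of the most abundant members where none was called, and 5 genes for each class of genes called in both lines. Some genes taken by the rule are not reported here, and counts of named genes leave them out, whereas list tests and gene counts keep them. Genes named outside this rule are stated to have been chosen after their values were seen.

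Alternatives changed the pseudocount to 0.1, the filter to a mean FPKM of 0.1 or 5 or none, the scaling to a common total or to median-of-ratios factors, the variance model to a robust one, the weights to estimated library weights, and the design to one with the replicate number as a block, and left out each library in turn. Centring each library per chromosome, and, in the comparison of the lines, leaving out libraries and taking only the members tested in both lines, were added after seeing the data. Fits that left out wild-type B16-F10 libraries in pairs were run after seeing the data and are not used here, because the pairs had been picked from the expression values themselves. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.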

Results

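Messenger RNA was measured by sequencing in 15 libraries from 2 mouse tumour lines in which the level of Ssbp4 was altered. MC38, a colon adenocarcinoma line, was represented by 4 wild-type libraries and 3 libraries from cells carrying a retroviral Ssbp4 expression vector. B16-F10, a melanoma line, was represented by 4 wild-type libraries that had received a control guide RNA and 4 libraries from cells given a pool of guide RNAs against Ssbp4 with Cas9. Ssbp4 encodes a single-stranded DNA binding protein family member, a family known to bind the LIM-domain cofactor Ldb1. The series title names tumour immune evasion and cholesterol biosynthesis, so genes of both themes were listed before the data were examined. Sequencing depth, estimated from the spacing of low FPKM values, was 32.6 to 38.5 M fragments per library in MC38 and 32.6 to 48.9 M in B16-F10. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

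Ssbp4 mRNA followed the labels in every library. In MC38 it stood at 16.3 ± 2.05 FPKM (SD, n = 4) in wild type and 534 ± 63.5 FPKM (SD, n = 3) in overexpressing cells, a log2 fold change of 4.95 (SE 0.10, adjusted p = 1.12e-09). In B16-F10 it stood at 34.5 ± 2.37 FPKM (SD, n = 4) in wild type and 22.1 ± 2.29 FPKM (SD, n = 4) in knockout cells, a log2 fold change of -0.62 (SE 0.08, adjusted p = 0.00869). The knockout level was 64.1% of wild type, and each knockout library, at 19.0 to 24.4 FPKM, lay below each wild-type library, at 32.4 to 37.4 FPKM. The two-sided exact permutation test gave p = 0.0286 in both lines, the smallest these designs allow. Reads from the vector and from the endogenous gene cannot be separated in these values, and transcripts carrying small insertions or deletions can persist, so mRNA does not gauge the protein lost.

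**Figure D1:**
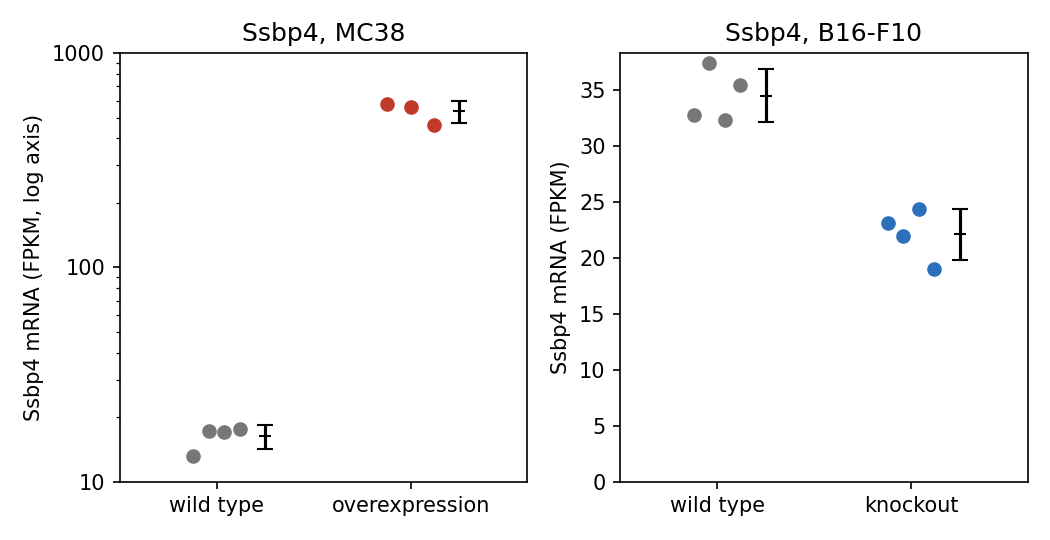
Ssbp4 mRNA in FPKM for each library of MC38 (left, log axis) and B16-F10 (right), with each group's mean and SD beside the points. The overexpressing MC38 libraries sit between 462 and 581 FPKM against 13.2 to 17.6 in wild type, and the knockout B16-F10 libraries sit below the wild-type ones.

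The first comparison asked which transcripts differed between MC38 cells overexpressing Ssbp4 and wild-type MC38 cells. All 20 tested enzymes of cholesterol synthesis and all 31 tested interferon-stimulated genes rose, as did 11 of 14 genes of fatty acid synthesis, 24 of 28 genes of hypoxia and glycolysis and 9 of 12 chemokines and cytokines. Among passing genes whose groups did not overlap and whose higher group mean was at least 5 FPKM, the largest rises on the log2(FPKM + 1) scale besides Ssbp4 were those of Crabp1, a cytoplasmic retinoic acid binding protein, from 0.788 ± 0.257 to 33.1 ± 1.75 FPKM, and of Penk, the enkephalin precursor, from 3.95 ± 0.581 to 54.3 ± 1.37 FPKM (SD, n = 4 and 3). On that scale and among those genes the largest falls were those of Avil, the actin-binding protein advillin, from 6.60 to 0.250 FPKM, and of Cdsn, corneodesmosin, from 7.94 to 0.490 FPKM. The order depends on the scale, since with a pseudocount of 0.1 Rgs5 (4.83) and Asb4 (4.29) rose more than Penk (3.76), and Krt18 (-4.50), which stayed under 5 FPKM, fell more than Avil (-4.26) and Cdsn (-3.80). In all, 5107 of 10748 tested genes passed an adjusted p of 0.05, of which 2567 rose and 2540 fell. Changes of at least 2-fold were seen in 220 genes, 176 up and 44 down. The groups did not overlap for 50.6% of tested genes, where chance gives 5.71%.

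Other transcripts that rose strongly were Asb4 (log2 fold change 3.16), Rgs5, a regulator of G protein signalling (3.05), Enpp2, the lysophosphatidic acid producing enzyme autotaxin (2.97), the metalloprotease Adam19 (2.87, SE 0.07) and the scavenger receptor Scara5 (2.83). Strong falls were also seen for the carbonic anhydrase Car6 (-2.35), Steap1 (-2.05), the muscle-type cytochrome oxidase subunit Cox6a2 (-1.91), Stbd1, a glycogen-binding protein (-1.59), and Paqr3 (-1.57). Prl2c3 fell by 1.76, but it has near-identical paralogs among which reads may be shared. All of these had an adjusted p of at most 1.16e-07. The first principal component held 74.8% of the variance and separated the overexpressing libraries, at 20.5 to 21.1, from wild type, at -16.0 to -15.0.

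Every tested cholesterol enzyme rose with overexpression. The list had 20 tested members, 20 higher and 0 lower, with 20 higher when adjusted over the list alone, a mean log2 fold change of 0.64 and a median of 0.73. Mvd, the mevalonate diphosphate decarboxylase, rose from 2.41 to 8.00 FPKM (log2 fold change 1.40), and Acat2, which condenses acetyl-CoA at the start of the pathway, rose by 1.15 on that scale. Hmgcs1 rose by 0.80 and Cyp51 by 0.87, whereas Sqle and Lbr rose by only 0.13 and 0.15. As a set the enzymes stood above other genes in a competitive list test (adjusted p = 3.48e-11; adjusted p = 0.0445 with an estimated correlation). Without overexpressing library 1, Mvk and Lbr no longer passed (adjusted p = 0.0583 and 0.0505).

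Sterol sensing and uptake genes had 8 of 15 tested members higher and 2 lower (9 and 2 adjusted over the list alone). Insig1, the endoplasmic reticulum anchor of the sterol sensor, rose from 13.5 to 36.8 FPKM and the sterol carrier Stard4 from 7.55 to 15.3 FPKM, while Scap fell by 0.28 and the protease Mbtps1 by 0.14, the latter not passing without overexpressing library 1 (adjusted p = 0.0684). The list passed its test (adjusted p = 0.00528) but not when the correlation was estimated (adjusted p = 0.105 with an estimated correlation). Fatty acid synthesis genes had 11 of 14 higher and 1 lower (11 and 1 adjusted over the list alone), led by Acss2, from 1.34 to 4.53 FPKM, and the desaturase Scd1, from 38.4 to 69.4 FPKM, with Mid1ip1 lower (-0.33). That list passed at adjusted p = 9.94e-06 and had adjusted p = 0.0848 with an estimated correlation. Of 8 tested LXR target and efflux genes, 3 rose, among them the lipid droplet protein Plin2 (0.55) and Lpcat3 (0.36), and 1 fell, the sterol esterifying enzyme Soat2 (-1.11). The same 3 and 1 passed when adjusted over the list alone, and the list did not pass (adjusted p = 0.400).

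**Figure D2:**
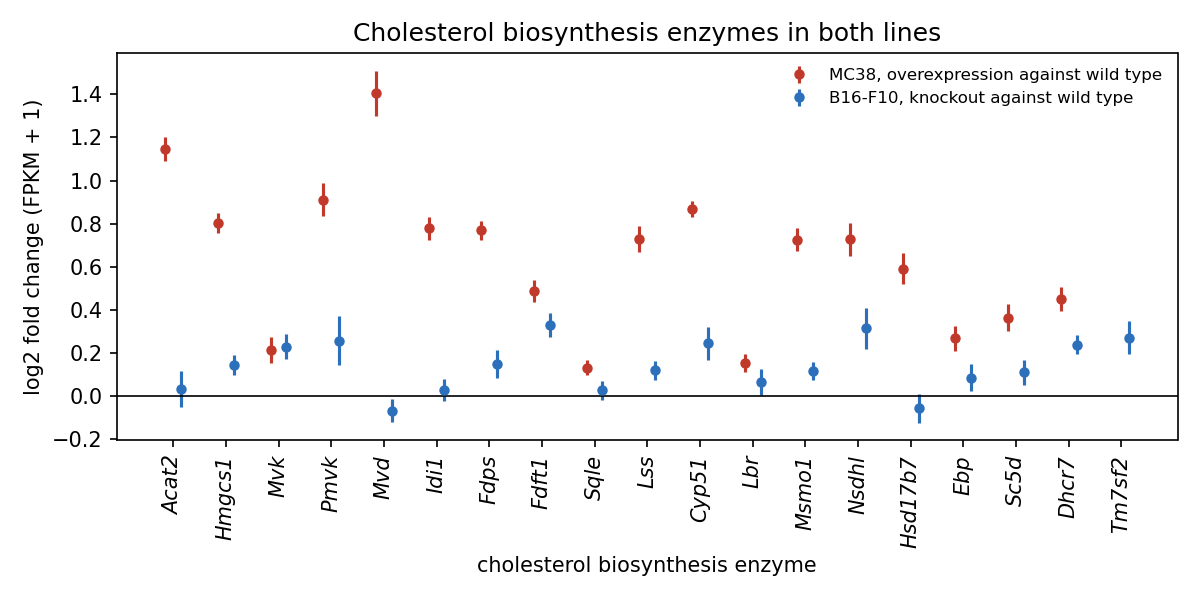
Log2 fold change on the FPKM + 1 scale, with its SE, for cholesterol biosynthesis enzymes in MC38 (overexpression against wild type) and B16-F10 (knockout against wild type). All MC38 values shown lie above 0, and the B16-F10 values shown lie between -0.07 and 0.33.

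Interferon-stimulated genes rose together, 31 of 31 tested members and 31 adjusted over the list alone, with a mean log2 fold change of 1.15. Ifi44 rose from 0.711 to 10.2 FPKM and the receptor transporter Rtp4 from 1.61 to 10.6 FPKM. The list passed with the preset correlation (adjusted p = 9.42e-21) and with an estimated one (adjusted p = 0.0281 with an estimated correlation). Among MHC class I presentation genes 14 of 21 rose and 4 fell (14 and 5 adjusted over the list alone). The peptide-loading chaperone Calr rose by 0.61 and the immunoproteasome subunit Psmb9 by 0.51, whereas the class I transactivator Nlrc5 fell by 0.49 and H2-Q7, which has close paralogs, by 0.31. The list passed at adjusted p = 0.00869, with adjusted p = 0.255 with an estimated correlation. Chemokines and cytokines had 9 of 12 higher and 1 lower (9 and 1 adjusted over the list alone), including the chemoattractants Ccl5, from 1.95 to 9.40 FPKM, and Ccl2, from 18.3 to 49.0 FPKM, with Csf1 lower (-0.74). That list had adjusted p = 2.51e-04, and adjusted p = 0.0565 with an estimated correlation. Immune checkpoint and ligand genes had 4 of 9 higher, including Lgals9 (1.31) and Pvr (0.59), and 3 lower, including Nectin2 (-0.27) and Raet1e (-0.25), with 4 and 3 adjusted over the list alone, and did not pass as a list (adjusted p = 0.309). Raet1e did not pass without any 1 of 5 libraries, the overexpressing libraries 1, 2 and 3 (adjusted p = 0.0761, 0.0994 and 0.0914) and wild-type libraries 1 and 3 (0.0673 and 0.0612).

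Hypoxia and glycolysis genes had 24 of 28 members higher and 1 lower (25 and 1 adjusted over the list alone), led by the mitophagy receptor Bnip3, from 58.5 to 124 FPKM, and Ankrd37 (1.00), with Pfkfb3 lower (-0.30). The list had adjusted p = 8.10e-10, and adjusted p = 0.0848 with an estimated correlation. Cytosolic ribosomal protein genes had 17 of 30 lower and 0 higher (18 lower adjusted over the list alone), for example Rpl18 (-0.30) and Rps19 (-0.28), with adjusted p = 2.51e-04, and adjusted p = 0.440 with an estimated correlation. In the stress response list 11 of 30 rose, including the chaperones Dnajb9 (0.57) and Pdia6 (0.57), and 16 fell, including Trib3 (-1.04) and Ddit3 (-1.01), both targets of the integrated stress response, with 11 and 16 adjusted over the list alone (adjusted p = 0.309). Of 10 Wnt target genes 6 rose, including Apcdd1 (1.97) and Wnt5a (1.02), and 3 fell, including Myc, from 183 to 94.3 FPKM, and Lef1 (-0.51), with 6 and 3 adjusted over the list alone (adjusted p = 0.309). Of 13 genes of the LDB1, LMO and SSBP family 4 rose, including Isl1 (0.82) and Lmo4 (0.30), and 7 fell, including Ssbp2, from 14.5 to 6.59 FPKM, and Lmo1 (-0.52), with 4 and 8 adjusted over the list alone (adjusted p = 0.309).

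The remaining MC38 lists did not pass in camera with the preset correlation on all libraries. TGF-beta and mesenchymal genes had 7 of 18 higher, including the collagen Col3a1 (1.49) and Thbs1 (0.55), and 6 lower, including the transcription factor Snai2 (-1.39), with 8 and 7 adjusted over the list alone (adjusted p = 0.759). Targets of p53 had 6 of 19 higher, including Tnfrsf10b (0.48) and Ccng1 (0.43), and 7 lower, including Plk2 (-0.71) and Bbc3 (-0.55, with overlapping groups), with 6 and 7 adjusted over the list alone (adjusted p = 0.524). Cell cycle genes had 8 of 32 higher, including Cdc20 (0.25) and Ccnb2 (0.24), and 8 lower, including Ccne1 (-0.31, SE 0.04) and Mcm7 (-0.26), with 8 and 8 adjusted over the list alone (adjusted p = 0.863). Nuclear-encoded respiratory chain genes had 2 of 35 higher, Cox6c (0.14) and Sdha (0.10), and 7 lower, including Uqcrq (-0.50) and Cyc1 (-0.25), with 2 and 7 adjusted over the list alone (adjusted p = 0.101; 0.0387 without overexpressing library 3, 0.0448 without wild-type library 1, and 0.0161 to 0.487 over the other alternatives). Immediate early genes had 5 of 16 higher, including Klf4 (0.75) and Ier3 (0.61), and 5 lower, including Atf3 (-0.94) and Fosl1 (-0.42), with 5 and 5 adjusted over the list alone (adjusted p = 0.862). Histone genes had 3 of 6 higher, including H1f2 (1.01) and H2bc4 (0.69), with 3 adjusted over the list alone (adjusted p = 0.111; 0.0431 without overexpressing library 3, 0.0465 without wild-type library 4, and 0.0255 to 0.440 over the other alternatives). Mitochondrially encoded transcripts had 1 of 13 higher, mt-Atp8 (1.16), and 2 lower, mt-Nd4l (-0.58) and mt-Nd3 (-0.57), with 1 and 2 adjusted over the list alone (adjusted p = 0.863). The mean of that list was 0.0014 and its median 0.010, while its test pointed to a lower level. Both mt-Atp8 and mt-Nd4l overlap a neighbouring gene, so their values are uncertain. Without overexpressing library 1, Cdc20 and Sdha no longer passed (adjusted p = 0.0534 and 0.0563), nor did Sdha without overexpressing library 3 (0.0962) or wild-type library 3 (0.0535).

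Markers of other cell types were mostly below 1 FPKM in MC38 and were not tested as lists. Of the epithelial markers Krt8 rose from 3.22 to 9.45 FPKM and its partner keratin Krt18 fell from 3.23 to 0.0607 FPKM. The only tested leukocyte marker, Cd68, rose by 0.38 but did not pass without overexpressing library 1 (adjusted p = 0.0714), the only tested endothelial marker, Egfl7, fell by 0.48, and the only tested melanocyte marker, Gpnmb, stood at 74.4 and 76.8 FPKM (adjusted p = 0.277). By list test 7 lists were higher and 1 lower of 20 tested, of which 2, the cholesterol and interferon lists, held with an estimated correlation. Other splits of the 7 libraries gave up to 10 called lists, so the number of called lists did not exceed what regrouping gave, while no other split gave more than 1 changed gene. Other splits mix the groups and some keep part of the real difference, so neither count sets a chance level.

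The second comparison asked which transcripts differed between B16-F10 cells edited at Ssbp4 and control B16-F10 cells. The Id genes, inhibitors of helix-loop-helix transcription factors, fell. Id3 dropped from 66.1 ± 3.51 to 12.8 ± 4.68 FPKM (log2 fold change -2.34), Id1 from 10.5 ± 4.32 to 2.85 ± 0.934 FPKM (-1.52) and Id2 from 208 ± 13.6 to 122 ± 4.75 FPKM (-0.76; SD, n = 4 and 4). The butyrophilin Btn2a2 fell from 7.20 to 1.64 FPKM and the ubiquitin ligase Mid1 from 20.8 to 7.77 FPKM. The adhesion molecule L1cam rose from 2.73 to 7.18 FPKM and Fez1, which acts in axonal transport, from 26.5 to 48.5 FPKM.

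In all, 243 of 10902 tested genes passed, 145 higher and 98 lower, and 9 changed at least 2-fold, 2 up and 7 down. At an unadjusted p under 0.05 there were 2325 genes, and the groups did not overlap for 13.9% of genes, where chance gives 2.86%. Further falls were seen for the chemokine Cxcl10, from 6.97 to 3.34 FPKM, and the gap junction protein Gja1 (-0.75). Further rises were seen for Sparcl1 (0.89), Rnf157 (0.78), Cdc42ep1 (0.78), the stress-responsive Nupr1 (0.78) and the metalloprotease inhibitors Timp3 (0.71) and Timp1 (0.64).

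The count depended on single libraries. It was 27, 23 and 26 without knockout libraries 1, 2 and 3, 93, 119, 44 and 41 without wild-type libraries 1 to 4, and 414 without knockout library 4. The 2-fold count was 14 without knockout library 4. Of the 35 genes that passed and that the naming rule takes besides Ssbp4, 8 passed whichever library was left out, namely Id3, Id2, Btn2a2, Mid1, L1cam, Fez1, Nupr1 and Dnajc1. The others, among them Id1, Sparcl1, Rnf157, Cdc42ep1, Timp1, Timp3, Cxcl10 and Gja1, did not pass without some libraries. Without knockout libraries 1, 2 and 3 there were 25, 27 and 26 such genes, with adjusted p of up to 0.132, 0.163 and 0.154, and without knockout library 4 there was 1, Gxylt2 (adjusted p = 0.0612). Without wild-type libraries 1 to 4 there were 18, 14, 21 and 23, with adjusted p of up to 0.0891, 0.0827, 0.0931 and 0.114. The split of higher and lower calls also moved with scaling, from 59.7% higher to 72.8% when libraries were rescaled to a common total and to 39.8% with median-of-ratios scaling.

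Libraries of a B16-F10 group also differed from each other. On the first principal component, with 42.8% of the variance, wild-type libraries 1 and 2 lay at -9.43 and -10.4, libraries 3 and 4 both at 17.8, and the knockout libraries between -7.81 and -1.91. Differences between wild-type libraries were 5.38 and 5.74 times sampling noise (chi-square per degree of freedom) for 1 against 2 and 3 against 4, and 28.3 to 30.2 times for the other pairings, and this spread enters the variance against which knockout is tested. Knockout library 4 lay at -1.04 on the second component and the other knockout libraries at -11.1 to -8.68.

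**Figure D3:**
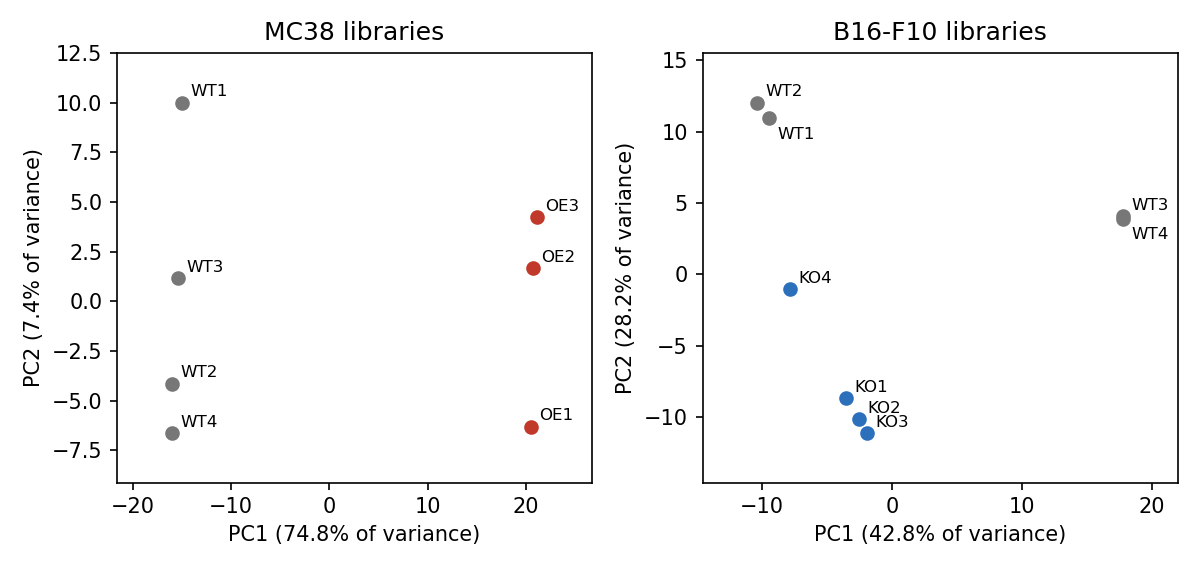
First and second principal components of log2(FPKM + 1) for the MC38 (left) and B16-F10 (right) libraries, each point a library labelled by group and replicate. MC38 libraries separate by group along a first component with 74.8% of the variance, whereas along that of B16-F10, with 42.8%, the knockout libraries lie between wild-type libraries.

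Cholesterol enzymes were not lower in knockout cells. Of 21 tested members 2 rose, Fdft1, squalene synthase, from 21.8 to 27.7 FPKM, and Dhcr7, the last reductase of the pathway, from 66.9 to 79.2 FPKM, and 0 fell, with 7 and 0 adjusted over the list alone. Without knockout library 4 both passed, without wild-type library 1 only Fdft1 did (Dhcr7 adjusted p = 0.0727), and without any other library neither did, the highest adjusted p being 0.131 for Fdft1 and 0.151 for Dhcr7. Fdft1 lies on chromosome 14, whose genes shifted together. With each library centred per chromosome, an alternative chosen after seeing the data, neither passed: for Fdft1 the log2 fold change was 0.18 (SE 0.04, adjusted p = 0.0697) in place of 0.33 (SE 0.06), mostly a smaller change, and for Dhcr7 0.20 (SE 0.05, adjusted p = 0.0760) in place of 0.24 (SE 0.05). Over the alternatives other than leaving out a library the adjusted p ranged from 0.00932 to 0.113 for Fdft1 and from 0.0185 to 0.158 for Dhcr7. Sqle stood at 63.7 and 64.9 FPKM (adjusted p = 0.762). The mean log2 fold change was 0.12, and the list passed with the preset correlation (adjusted p = 0.00290) and with fry (adjusted p = 0.00671) but not in camera with an estimated correlation (adjusted p = 0.627). LXR targets had 3 of 8 higher and 0 lower, including the cholesterol exporter Abca1 (0.41) and Lpcat3 (0.39), with 4 and 0 adjusted over the list alone (adjusted p = 0.00125; adjusted p = 0.627 with an estimated correlation). Their list scores were 5.12, 5.11, 4.85 and 4.80 in wild-type libraries 1 to 4 and 5.14 to 5.20 in knockout libraries, which lay above each wild-type library but close to 1 and 2. Of 14 fatty acid genes 2 rose, the desaturases Fads2 (0.34) and Fads1 (0.25), with 3 and 1 adjusted over the list alone (list adjusted p = 0.321). Sterol sensing genes had 0 of 15 called by limma, 6 higher and 2 lower at an unadjusted p under 0.05, and 3 and 2 adjusted over the list alone (list adjusted p = 0.248), with Npc2 at 81.6 and 85.9 FPKM and Insig1 at 66.6 and 75.9 FPKM.

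Immune gene lists did not pass with camera in B16-F10, while the interferon list, with a mean log2 fold change of 0.06 (0.035 without knockout library 2), passed with fry (adjusted p = 3.89e-04). Of 14 interferon-stimulated genes 0 were called by limma, with 1 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.498), Bst2 being at 20.6 FPKM in both groups and Ifit2 at 17.3 and 18.4 FPKM. Of 13 MHC class I genes 0 were called by limma, with 3 higher and 3 lower both at an unadjusted p under 0.05 and adjusted over the list alone (list adjusted p = 0.356), with Calr at 855 and 693 FPKM and Pdia3 at 388 and 363 FPKM. Of 8 chemokines and cytokines 1 fell, Cxcl10, also when adjusted over the list alone (list adjusted p = 0.321). Of 8 checkpoint and ligand genes 0 were called by limma, with 3 higher and 1 lower at an unadjusted p under 0.05 and 1 higher adjusted over the list alone (list adjusted p = 0.498), with Lgals3 at 129 and 203 FPKM and Cd47 at 14.5 and 16.8 FPKM.

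Ribosomal protein genes had 2 of 30 lower, Rps23 (-0.33) and Rpl10a (-0.33), and 0 higher, with 7 lower adjusted over the list alone (adjusted p = 5.36e-11; adjusted p = 0.627 with an estimated correlation). Targets of p53 had 2 of 19 lower, the kinase Plk2 (-0.55) and Trp53inp1 (-0.47), with 6 lower adjusted over the list alone (adjusted p = 1.13e-06; adjusted p = 0.627 with an estimated correlation). The p53 list scores were 4.49, 4.52, 4.25 and 4.25 in wild-type libraries 1 to 4 and 4.10 to 4.31 in knockout libraries. Hypoxia and glycolysis genes had 0 of 27 called by limma, 1 higher and 6 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Gapdh at 2315 and 2145 FPKM and Eno1 at 1660 and 1413 FPKM (list adjusted p = 0.00105; adjusted p = 0.627 with an estimated correlation). Their mean log2 level was 5.38, 5.42, 6.15 and 6.19 in wild-type libraries 1 to 4 and 5.47 to 5.61 in knockout libraries. The list mean, -0.22, ranged from -0.36 to -0.09 with single libraries left out, and the list did not pass without wild-type library 3 or 4 (adjusted p = 0.0566 and 0.0589). Immediate early genes had 0 of 13 called by limma, 1 higher and 4 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Klf6 at 20.5 and 23.8 FPKM and Nr4a1 at 20.3 and 18.8 FPKM (list adjusted p = 0.0442; adjusted p = 0.627 with an estimated correlation). Their scores were 3.20, 3.18, 2.57 and 2.56 in wild-type libraries 1 to 4 and 2.63 to 2.82 in knockout libraries. The list mean, -0.19, ranged from -0.29 to -0.08 with single libraries left out, and the list did not pass without wild-type libraries 1 or 2 (adjusted p = 0.387 and 0.287) or knockout libraries 1, 2 or 3 (0.0833, 0.0811 and 0.0762), nor with median-of-ratios scaling, a mean FPKM filter of 5, where the mean was only -0.015, or centring per chromosome. With library weights the mean was -0.30. The stress response list had 1 of 29 higher, Nupr1, also when adjusted over the list alone (list adjusted p = 0.0172 for a lower level; adjusted p = 0.627 with an estimated correlation), and scores of 6.17, 6.16, 6.36 and 6.38 in wild-type libraries 1 to 4 against 6.18 to 6.25 in knockout libraries. It did not pass without wild-type library 3 or 4 (adjusted p = 0.104 and 0.135), where its mean of -0.06 became -0.035 and -0.029.

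No other B16-F10 list passed in camera with the preset correlation on all libraries. Melanocyte markers had 0 of 19 called by limma, 4 higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.442), with Tyrp1 at 4494 and 4754 FPKM and Dct at 3183 and 4051 FPKM. Cell cycle genes had 0 of 32 called by limma, 2 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.276), with Pcna at 328 and 337 FPKM, Rrm2 at 244 and 242 FPKM, and scores of 5.82, 5.81, 6.18 and 6.18 in wild-type libraries 1 to 4. Its mean of 0.09 became 0.15 without wild-type library 3 or 4, 0.135 without knockout library 4 and 0.17 with library weights, where it passed as higher (adjusted p = 0.00327, 0.00401, 0.0480 and 0.00130), and 0.031 and 0.027 without wild-type libraries 1 and 2, where it did not (adjusted p = 0.949 and 0.973). Of 9 LDB1, LMO and SSBP family genes 1 fell, the LIM-domain cofactor Ldb1, from 116 to 99.5 FPKM, with 1 higher and 1 lower adjusted over the list alone (list adjusted p = 0.362). Ldb1 passed without knockout library 4 but not without any other single library (limma adjusted p of up to 0.158). It also fell with overexpression in MC38 (log2 fold change -0.17, limma adjusted p = 0.0190), a value chosen after it was seen. Of 8 Wnt targets 0 were called by limma, with 1 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.807). The mean of that list was 0.0068, while its median, -0.011, and its test pointed lower, with Cd44 at 109 and 115 FPKM and Ccnd1 at 60.9 and 59.1 FPKM. Of 16 TGF-beta and mesenchymal genes 0 were called, with 3 higher and 2 lower at an unadjusted p under 0.05 and 3 higher adjusted over the list alone (list adjusted p = 0.653), with Vim at 619 and 627 FPKM and Sparc at 454 and 528 FPKM. Of 35 respiratory chain genes 0 were called, with 1 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.498; 0.0364 with library weights), with Atp5b at 764 and 780 FPKM and Ndufa4 at 543 and 600 FPKM. Of 13 mitochondrially encoded transcripts 0 were called, 0 also at an unadjusted p under 0.05 and adjusted over the list alone (list adjusted p = 0.879), with mt-Cytb at 4577 and 4671 FPKM and mt-Co1 at 3586 and 3854 FPKM. Of 3 endothelial markers 0 were called, with 1 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone (list adjusted p = 0.321), with Eng at 107 and 113 FPKM and Egfl7 at 13.9 and 16.3 FPKM. Too few members were tested for the epithelial list (Lgals4 at 1.22 and 1.35 FPKM), the leukocyte list (Cd68 at 2.02 and 2.80 FPKM) and the histone list (H2bc4 at 5.78 and 6.74 FPKM, H1f2 at 5.97 and 6.55 FPKM). In B16-F10 2 lists were higher and 5 lower of 21 tested, 0 held in camera with an estimated correlation, where 1 had an unadjusted p under 0.05, and 3 passed with fry. Other splits of the 8 libraries gave up to 8 called lists, but some keep part of the real difference, so this sets no chance level.

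The third comparison set both lines side by side, asking whether raising and lowering Ssbp4 moved genes in opposite directions. The tables were normalised separately, so only each line's own fold changes were compared. Of 9739 genes tested in both lines, 12 were higher with overexpression and lower with knockout, among them Ssbp4 itself, the interferon-inducible chemokine Cxcl10, the connexin Gja1, the caveolar protein Cav1 and B4galt2, and 25 were lower and higher in turn, among them Hhipl1, Cdc42ep1, Adh7, Tshz1 and Dnajc1. Independent lists would give 15.6 and 28.4 (Fisher's exact test, adjusted p = 0.515 and 0.516). In the same direction in both lines, 49 genes were higher, where independent lists give 26.1, and 39 were lower, where they give 17.0 (Fisher's exact test, adjusted p = 3.62e-06 and 7.49e-08). These included Gxylt2 and the growth factor receptor Pdgfrb, higher in both lines, and Plk2 and Mid1, lower in both. Of the genes named in this comparison, only Ssbp4, Dnajc1 and Mid1 kept their B16-F10 call whichever library was left out. Genes are not independent replicates, although Fisher's exact test takes them as such, so its p-values may be too small. Across genes the fold changes had r = 0.12 and rho = 0.16. Of 100 regroupings of the libraries 12 gave an r as large in size. The counts rested on single B16-F10 libraries, being 4 opposite and 11, 8 and 8 alike without knockout libraries 1, 2 and 3, where independent lists give 3.97, 3.52 and 3.97 alike. Without wild-type libraries 1 to 4 they were 14 and 35, 18 and 31, 5 and 16, and 4 and 14. The excess of genes changed alike did not pass Fisher's exact test in both directions without knockout library 1, 2 or 3 (higher unadjusted p of both classes 0.0800, 0.130 and 0.389) or wild-type library 2 or 3 (0.221 and 0.155). Without knockout library 4 there were 135 alike, where independent lists give 74.2, and 56 opposite, fewer than the 76.3 they give (lower unadjusted p of both classes 1.36e-04). Without overexpressing library 2 the opposite count was 24, where they give 37.3 (0.0377).

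The change of each list from lower to higher Ssbp4, taken as overexpression minus wild type in MC38 and wild type minus knockout in B16-F10, was then compared between lines. For cholesterol enzymes it was 0.64 in MC38 and -0.12 in B16-F10, a difference of 0.76 (exact permutation test over 2450 arrangements, adjusted p = 0.00388 over 19 lists). For interferon-stimulated genes it was 1.15 and -0.06, a difference of 1.22 (exact permutation test, adjusted p = 0.00388). These means take the members tested in each line, 31 and 14 for interferon-stimulated genes. Over the members tested in both lines, an alternative chosen after seeing the data, the differences were 0.75 for 20 cholesterol enzymes and 0.97 for 14 interferon-stimulated genes (exact permutation tests, adjusted p = 0.00388 for both). The arrangements assume no effect in either line, so a strong effect in MC38 alone passes this test. Ssbp4 itself changed unequally, with a log2 fold change of 4.95 with overexpression and -0.62 with knockout, and the differences were not scaled for this.

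Genes of some chromosomes shifted together in each line, a limit on calls for single genes located there, such as Fdft1 on chromosome 14. In B16-F10 the median log2 fold change was 0.16 for the 355 tested genes of chromosome 14, of which 18 were called higher and 1 lower, and 0.12 for chromosome 18. With each library centred per chromosome, an alternative chosen after seeing the data, 155 genes were called in B16-F10, 38.1% of them higher.

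**Figure D4:**
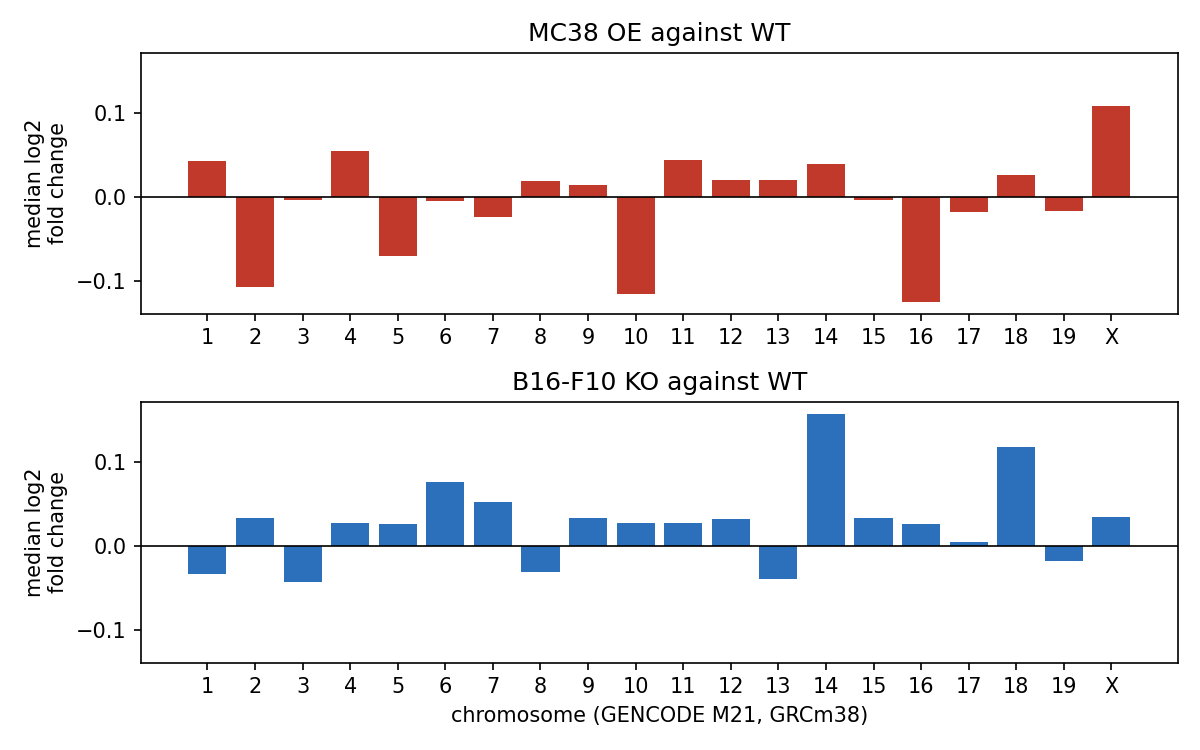
Median log2 fold change of the tested genes on each chromosome (GENCODE M21, GRCm38) in MC38 overexpression (top) and B16-F10 knockout (bottom) against wild type. In B16-F10 chromosome 14 stands highest at 0.16, and in MC38 chromosome 16 stands lowest at -0.12.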

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

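Tests of scaling, cell type, chromosome and spread in this part were chosen only after the results were seen, except the counts over other splits for chromosome shifts, 2-fold genes and lists.

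Samples far from the other samples of their group were sought in 344 groups of 4 values, by the gap to the nearest value over the range. There were 26, where chance gives about 5% of groups, or 17.2. In B16-F10 knockout cells 13 of them were library 4. Its values lay apart for Id3 (19.8 FPKM against 9.95 to 10.8 in the other libraries, ratio 0.918), Gja1 (0.879), Calr (0.969), Lgals3 (0.962), Dct (0.846), Trp53inp1 (0.866), Atp5b (0.884), Acat2 (0.846) and Dnajc1 (0.8292), and for the lists of chemokines (0.841), p53 targets (0.866), cell cycle (0.923) and immediate early genes (0.865). Library 4 also had the lowest Ssbp4 mRNA of the knockout libraries, 19.0 FPKM. Knockout library 1 stood apart for Ifit2 (0.849) and knockout library 2 for H1f2 (0.881). Among MC38 wild-type libraries, library 1 stood apart for Ssbp4 (13.2 FPKM against 17.0 to 17.6, ratio 0.873), Cdsn (0.902), Myc (0.845) and Dnajc1 (0.971). Library 2 did for Acat2 (0.895), Mbtps1 (0.866), Acss2 (0.892) and Sqle (0.844), and library 3 for Snai2 (0.961), H1f2 (0.833) and Cav1 (0.842).

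The exact permutation test of the difference between the lines passed for 11 of 19 lists (adjusted p under 0.05). Its arrangements assume no effect in either line, so a change in MC38 alone or in B16-F10 alone passes. Whether the lines responded unequally was not tested. The difference, MC38 minus B16-F10, was 0.76 for cholesterol enzymes, 1.22 for interferon-stimulated genes, 0.49 for fatty acid synthesis, 0.39 for sterol sensing, 0.34 for checkpoint genes, 0.23 for LXR targets and 0.21 for Wnt targets. It was -0.295 for ribosomal proteins, -0.27 for p53 targets, -0.16 for the stress response and -0.11 for the LDB1 family. The B16-F10 part, wild type minus knockout, was the larger for p53 targets (-0.056 in MC38 and 0.21 in B16-F10) and LXR targets (0.032 and -0.20). For ribosomal proteins the parts were alike in size (-0.15 and 0.15), with lower levels in both altered groups. For the other lists that passed, MC38 gave the larger part. Over the members tested in both lines, an alternative chosen after seeing the data, the Wnt difference was -0.093 over 7 genes in place of 0.21, with its sign changed (exact permutation test, adjusted p = 0.0155), so its direction rests on which members are taken. Over those members the LDB1 family difference was -0.24 (9 genes) and the LXR difference 0.37 (7 genes), each over 1.5 times its size over the members of each line. The LXR difference had an unadjusted exact permutation p of 0.0661, 0.0547 and 0.0547 without knockout libraries 1, 3 and 4, and 0.129 with a pseudocount of 0.1 (0.0180 with median-of-ratios scaling and 0.00122 over the members tested in both lines). The stress response difference had 0.0531 and 0.0522 without knockout libraries 2 and 3, and 0.0555 and 0.0571 without wild-type libraries 3 and 4, by the same exact test.

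Cholesterol and interferon-stimulated genes were higher in MC38 overexpressing cells. Library scaling moves all genes alike, and the median over all tested genes was -0.0088, far from the list mean of 0.64. Leukocyte RNA is argued against by Ptprc, Tyrobp, Laptm5 and Coro1a, whose highest mean in overexpressing cells was 0.0971 FPKM. Transduction itself, or outgrowth of a subset of cells, may account for the rise, and cannot be told apart from the Ssbp4 level, because the labels name 0 MC38 groups other than these. An effect of Ssbp4 stays open as well.

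In B16-F10 knockout cells the genes of chromosome 14 (GENCODE M21, GRCm38) were higher together, with a median log2 fold change of 0.16 over 355 genes. Genes on other chromosomes had a median of 0.020, which argues against scaling, and 85.4% of chromosome 14 genes lay above the median of all genes, which argues against a few strong genes. Each knockout library lay above each wild-type library, by at least 0.021, although knockout library 4, at -0.03, was closer to wild type, at -0.07 to -0.05, than to the other knockout libraries, at 0.08 to 0.11. The real grouping gave the largest chromosome shift, 0.13, in 1 of 35 splits. The highest other, 0.12, exchanged knockout library 4 with wild-type library 1. Ranking first by so little does not exclude an accidental division of the libraries. All 7 windows of 50 neighbouring genes were shifted, the lowest by 0.12, so an extra copy in part of the knockout cells is a candidate explanation, a hypothesis found and tested on the same data.

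Cholesterol enzymes were not lower in B16-F10 knockout cells. A fall hidden by the spread of wild-type libraries is argued against by the list scores, the lowest knockout score being 0.047 above the highest wild-type score. Shifts of whole chromosomes are argued against as the cause, since the list mean was 0.120 before and 0.119 after centring per chromosome. Incomplete loss of Ssbp4 may account for the absence of a fall. It cannot be told apart from a lack of effect, because mRNA at 64.1% of wild type does not show how much protein was left. Neither accounts for the small rise of the mean list score, from 5.07 in wild type to 5.19 in knockout. That rise did not pass in camera with an estimated correlation (adjusted p = 0.627), and its cause was not tested.

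Whether an accidental division of the libraries gives as much was tested with all 35 splits of each line. In MC38 1 split, the real one, gave as many changed genes (5107, highest other 1) and as many changed 2-fold (220, highest other 1). In B16-F10 1 split, the real one, gave as many changed genes (243, highest other 2) and as many changed 2-fold (9, highest other 2). The real grouping thus ranked first of 35 for these counts, the highest rank these splits allow. Other splits mix both groups, so a real difference adds to their within-group spread and lowers their counts. The ranks alone therefore do not exclude chance. The number of called lists did not stand out, since 10 of 35 splits in MC38 (real 8, highest other 10) and 12 of 35 in B16-F10 (real 7, highest other 8) gave as many. In MC38 some of these splits keep part of the real difference, so they set no chance level either. For genes called in both lines such a count also decides nothing. Of 101 regroupings of both lines 1, the real one, gave as many in opposite directions (37, highest other 0) and in the same direction (88, highest other 0), but the other splits call at most 1 gene in MC38 and 2 in B16-F10, so their shared count was bound to be near 0. Against lists drawn independently, 37 was no excess over the 44.0 expected.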

How the results depend on the processing

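Alternatives were set out before the data were examined, except centring per chromosome and, for the comparison of the lines, the leave-out fits and the lists reduced to members tested in both lines. In MC38 the cholesterol and interferon lists kept their direction and side of the threshold under every alternative run, with list means of 0.59 to 0.69 and 0.92 to 1.58. The MC38 gene count stayed within 1.5 times 5107, from 3906 to 5463. The Ssbp4 level was run only with a pseudocount of 0.1, median-of-ratios scaling, the replicate block, centring per chromosome and single libraries left out, and did so in MC38 under each of these and in B16-F10 under each but the block. Depth limits genes near 1 FPKM, which rest on about 32.6 to 48.9 fragments per kilobase. Count models (edgeR, DESeq2) were not run, since the values are FPKM. The cause of the shifts below was not tested unless stated.

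The count of changed B16-F10 genes, 243, became 140 with a mean FPKM filter of 0.1 and 73 with no filter, where more genes were tested, 776 with library weights, 155 when centred per chromosome, and 23 to 414 with single libraries left out. The 2-fold count, 9, became 19 with a pseudocount of 0.1, 5 with a filter of 5, 15 with library weights, and 7 to 14 with single libraries left out. The MC38 2-fold count, 220, became 119 with a filter of 5, where fewer genes were tested.

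Genes called in both lines in opposite directions, 37, became 20 with a filter of 5, where independent lists give 30.9, 2 at adjusted p 0.01, 0 with a 2-fold change in both, 24 with median-of-ratios scaling, fewer than the 35.6 they give (lowest unadjusted Fisher's exact p 0.0464), 24 when centred per chromosome, where they give 26.0, and 4 to 56 with single libraries left out. In the same direction, 88 became 6 at adjusted p 0.01, where independent lists give 2.26 (highest unadjusted Fisher's exact p 0.301), 0 with a 2-fold change, 58 when centred and 8 to 135 with single libraries left out.

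Called lists numbered 2 in MC38 and 0 in B16-F10 with an estimated correlation, and 17 and 3 with fry. The B16-F10 cholesterol list, with a mean of 0.12, did not pass with an estimated correlation (adjusted p = 0.627).

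Replicate numbers showed no pairing of samples. With each gene's group mean taken off, same-numbered libraries had correlations of -0.29, -0.07 and -0.07 in MC38 and -0.11, -0.18, 0.17 and -0.30 in B16-F10. Those of unlike-numbered libraries ranged from -0.20 to 0.26 in MC38 and from -0.27 to 0.29 in B16-F10. With the number as a block 12 B16-F10 and 3906 MC38 genes were called, and the B16-F10 Ssbp4 change of -0.62 had adjusted p = 0.0890.

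Of 4474 values of single genes and lists under the alternatives, 4074 stayed on their side of the threshold in the same direction, 306 lost a call, 33 gained one and 61 changed sign or test direction. For the 13 main results, which include the gene counts, 182 of 231 values stayed the same, counts being held the same within 1.5 times. Of the main values 41 were weaker, 8 stronger and 0 reversed. Of the named genes called in MC38, Bbc3, Cd68, Cdc20 and Raet1e did not pass with no filter (adjusted p 0.0618, 0.0785, 0.0652 and 0.130), Raet1e also with a filter of 0.1 (0.0533) and rescaled to a common total (0.0568), Raet1e and Sdha when centred (0.202 and 0.0584), and Cox6c, Cyc1, Lbr, Mbtps1, Mvk, Rps19, Sdha and Sqle with the replicate block (0.05002 to 0.127). Of 35 in B16-F10, 10 passed under every alternative other than the block and single libraries left out. Values that changed sign or test direction were all uncalled except the Wnt difference between lines, which passed both as 0.21 and, over the members tested in both lines, as -0.093. The TGF-beta difference, 0.090, was -0.076 over those members. With median-of-ratios scaling these were Bst2 (-0.020), Rrm2 (-0.020), Vim (-0.0041) and the Wnt list (-0.014) in B16-F10. When centred they were Rrm2 (-0.028), Sqle (-0.0080), Vim (-0.0097) and the Wnt list (-0.0064). With library weights they were Eng (-0.0027), Vim (-0.0011), the melanocyte (0.017), TGF-beta (0.023) and Wnt (-0.0031) lists, and in MC38 the mitochondrial list (-0.038). With filters of 0.1, 5 and none the B16-F10 Wnt list stood at -0.017, 0.060 and -0.0073. The B16-F10 interferon list stood at -0.028 with a filter of 0.1 and -0.023 with none, the TGF-beta list at 0.024 with none, and the LDB1 and MHC lists at 0.0086 and 0.0054 with a filter of 5. In MC38 the LXR list stood at -0.018 with a pseudocount of 0.1 and the mitochondrial list at 0.052 with the block. The direction of fry differed from that of camera for the Wnt list (0.0068) and, in MC38, the cell cycle (0.0085) and mitochondrial (0.0014) lists.

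With single libraries left out, B16-F10 ranges that held a change of sign or of test direction were -0.031 to 0.081 for Acat2, -0.014 to 0.080 for Atp5b, -0.011 to 0.021 for Bst2, -0.092 to 0.027 for Ccnd1, -0.0094 to 0.058 for mt-Cytb and -0.081 to 0.085 for Rrm2. For lists they were 0.027 to 0.15 (cell cycle), -0.032 to 0.0038 (LDB1 family), 0.0041 to 0.15 (melanocyte), 0.0031 to 0.066 (mitochondrial) and -0.0055 to 0.021 (Wnt). In MC38 they were -0.011 to 0.049 (immediate early) and -0.056 to 0.056 (mitochondrial), and the mitochondrial difference between lines ranged from -0.018 to 0.094.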

Other observations

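Apart from the limma tests, the tests in this part were chosen only after the results were seen. Apart from Krt8 and Krt18, the listed epithelial genes had a mean under 1 FPKM in MC38 and were outside the tested set. Epcam, an epithelial adhesion molecule, stood at a mean of 0.847 FPKM in wild type and was listed at 0 in overexpressing cells, Cdh1, E-cadherin, at 0.306 and 0.0333 FPKM, and Krt7 at 0.686 and 0.171 FPKM (n = 4 and 3), all chosen after their values were seen.

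In MC38 the chromosomes with the largest shifts were X (median log2 fold change 0.11), 16 (-0.12), 10 (-0.12) and 2 (-0.11), and in B16-F10, after 14, chromosome 18 (0.12 over 254 genes).

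Id1, Id2 and Id3 are targets of BMP-SMAD signalling, and a hypothesis is that expression of its targets was lower in B16-F10 knockout cells. Of 5 further targets chosen after their values were seen, 3 were lower in every knockout library than in every wild-type library, namely Smad6 (1.25 and 0.554 FPKM), Smad9 (1.98 and 0.883 FPKM) and Atoh8 (2.17 and 1.07 FPKM). Smad7 (3.22 and 2.92 FPKM) and Bambi (2.87 and 3.42 FPKM) were not. No p-value is given, since the targets were chosen after the fall of the Id genes and their own values were seen. With 3 of 5 lower the hypothesis stays open. In MC38, Id1 stood at 7.08 and 6.23 FPKM in wild-type and overexpressing cells (limma adjusted p = 0.344), while Id2 fell from 30.9 to 28.1 FPKM (log2 fold change -0.13, limma adjusted p = 0.0340), Id3 from 21.8 to 17.1 FPKM (-0.33, limma adjusted p = 0.00413) and Smad7 from 9.67 to 7.27 FPKM (-0.37, limma adjusted p = 9.95e-04), all chosen after their values were seen. Of the other targets, Smad6 stood at 1.145 and 0.875 FPKM and Atoh8 at 0.539 and 0.482 FPKM. Bambi stood at 0.127 and 0.261 FPKM and Smad9 at 0.0541 and 0.0667 FPKM. Atoh8, Bambi and Smad9 lay under the filter of 1 FPKM in MC38, so no change is read from them.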
